A study of Mus musculus with 16 samples.

How the data were processed

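RNA of the right kidneys of 5 wild-type male littermate mice, W1 to W5, was compared on 16 two-colour microarrays. Each array held W5 in one channel and W1, W2, W3 or W4 in the other, with 4 arrays per mouse. On 8 arrays the mouse was in channel 1, and on the other 8 arrays W5 was. The mice had a mixed C57BL/6 and 129Sv background and were killed at 88 ± 2 days of age between 8 and 10 in the morning, per the labels. Per the labels, total RNA was prepared with RNeasy columns and 20 µg were reverse transcribed and labelled indirectly with Cy3 or Cy5. Hybridisation ran at 42 °C for 18 to 20 hours, also per the labels. Slides were read with a GenePix 4000A scanner and GenePix Pro 3.0, per the labels.

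The deposited values are log2 ratios of the 2 channels of an array, made by the authors from background-subtracted mean intensities scaled to a median ratio of 1. The log base was settled from the values, since between 1.56% and 5.01% of the values per array lay within 2e-06 of log2 of a ratio of whole numbers up to 12. Under natural logs this share was at most 0.0345%, and under log10 at most 0.127%. Medians per array lay between -0.0225 and 0.00435. Which dye each channel carried, which channel is the numerator, and what filter lies behind the empty cells are not given in the sources used here. An array had values for 16209 to 18406 of 20205 probes, which is 80.2% to 91.1%. For arrays, the number of hybridisations and of animals limits the precision.

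Arrays with W5 in channel 1 had their sign turned before fitting. The rule, fixed before the data were examined, took the correlation across probes of a mouse's arrays of opposite orientation, after centring each probe over the mice within an orientation. Genes are not independent replicates in this correlation. It was -0.156 in W1, -0.0759 in W2, -0.0658 in W3 and -0.107 in W4, below 0 in each mouse. The 2 arrays of the same orientation correlated at 0.115 and 0.0206 in W1, 0.0976 and -0.0111 in W2, -0.0506 and 0.0300 in W3, and -0.133 and -0.236 in W4, so in W4 this correlation does not tell the orientations apart; centring itself lowers values within an orientation. Probes beyond 0.3 in both orientations had opposite signs in 78, 85, 94 and 148 cases in W1 to W4, and the same sign in 18, 47, 57 and 79. Before turning, arrays of different mice in the same orientation had a correlation between 0.0256 and 0.418. Arrays of a mouse in opposite orientations had one between -0.197 and 0.102. These spans overlap, so a value above 0 cannot show that no array ran against the others. Since the numerator is open, sizes are given without saying which kidney was higher. Side A denotes the side of W5 on which Serpina1e lay in all 4 mice, and side B the opposite side.

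Probes with values on at least 3 of the 4 arrays of every mouse were tested, 15715 in all. The limma package (3.58.1, in R 4.3.3) fitted 4 mouse coefficients against W5 and a gene-specific dye term with lmFit and eBayes. One moderated F test asked whether all 4 coefficients are 0, which is whether any of the 5 kidneys differ. A second F test used the 3 differences among W1 to W4, where W5 cancels. The 10 pairs of kidneys and the dye term were tested with limma's moderated test, all two-sided. The arrays of a mouse are repeat hybridisations of the same RNA extracts, so these tests concern these extracts and not a population of mice. W5 was set against its littermates with the 4 arrays of each mouse averaged and the 4 means tested against 0 with limma, which leaves out the spread of W5 itself. P-values were adjusted by Benjamini-Hochberg over all probes tested within each question, and a probe was called at an adjusted p under 0.05. Technical and between-kidney variances came from the mean squares of the fit, with the standard error of their medians from a jackknife over arrays.

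On simulated arrays in which 1 mouse was moved at 50 probes per size, the 5-kidney test recovered 0% at 1.25-fold, 48% at 1.5-fold, and 100% at 2-fold and at 3-fold, with 7 calls among 15515 unchanged probes. The test among W1 to W4 recovered 0%, 34%, 98% and 100% at these sizes, with 4 calls among unchanged probes. With all mice moved 2-fold, the W5 test recovered 100% of 200 probes and made 17 calls among unchanged ones. That simulation had independent errors, a between-mouse variance of 0.01 and no deviation of W5 itself at unchanged probes. The real W5 has a spread of its own, so these rates do not carry over to the real W5 test.

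Probes were named through a table of the platform's annotation. Of the 20205 probes, 11723 had 1 gene symbol, 806 had several and 7676 are unnamed here. Of the single-gene probes, 11590 were matched to a gene table of assembly GRCm38.p6, used only for names and for neighbouring genes, and 0 symbols changed. For a gene with several probes, the probe measured on most arrays was used, then the first identifier, which gave 8005 named genes tested. No gene is named from a probe with several.

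Of the gene lists fixed before the data were examined, 30 had at least 5 measured genes. Each list's count of called genes was tested against all named genes with a one-sided Fisher's exact test, and again adjusted over the list alone. Its median between-kidney variance was placed among 10000 random lists of the same size. Limma's camera compared each list with other genes in each pair of kidneys, with a preset correlation of 0.01 and again with an estimated one, adjusted over all 300 tests. Camera used the 6158 named genes with values on all arrays.

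The genes named in the text follow a rule fixed at the same time. It took the 20 called genes with the largest range over the kidneys whose 4 arrays share a sign in the mouse farthest from W5. It added up to 4 called genes of each list with the largest range, and for each kidney the 5 called genes for which it lay farthest from the median of the others. It further added the 5 genes of largest size on either side in the W5 test, and Actb, Gapdh and Hprt as controls. Gapdh and Hprt were not among the probes tested and are not analysed here.

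Alternatives fixed before the data were examined covered the probe filter, scaling or quantile normalization between arrays, the dye term, the array number as a block, array weights, robust or no variance moderation, a stricter threshold, 1 probe per gene, and each array or mouse left out. For the W5 test they also covered a random block for the mouse and an added spread for W5. Alternatives chosen after seeing the data left out 2423 dim probes, took off a running median over 21 neighbouring probe numbers, or left out the 2 dimmest arrays, W4.3 and W4.4. A probe was called dim where the smallest whole-number pair that gives its ratio had a median under 100. That pair is a stand-in for brightness, because no intensities were used here. Neighbouring probe numbers correlated within an array between 0.0306 and 0.209, and after shuffling between -0.0141 and 0.0098, which was the reason for the running median. Whether probe numbers follow positions on the slide is not given in the sources used here. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 prepared the tables and figures.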

Results

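Transcript levels in the right kidneys of 5 wild-type male littermates were compared to measure normal variation between individual mice. Kidneys W1, W2, W3 and W4 were each hybridised against the kidney of W5 on 4 arrays, 2 in each channel orientation, giving 16 arrays. Array W3.2, for example, is array 2 of W3. Values are log2 ratios against W5 with the standard error (SE) of the fit over n = 4 arrays per mouse, and are given as sizes because the direction against W5 is not settled. Side A is the side of W5 on which Serpina1e lay in all 4 mice, and side B is the opposite side. A range is the distance between the outermost of the 5 kidneys, with W5 at 0. Each array gave values for 80.2% to 91.1% of its 20205 probes.

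The first comparison asked which transcripts differed among the 5 kidneys. Among named genes, Serpina1e had the largest range and Pttg1 followed. Serpina1e and Serpina1b, alpha-1-antitrypsin type protease inhibitors, lay on side A in all 4 mice. Serpina1e reached 2.81 ± 0.09 in W2, a range of 7.02-fold, with 1.89 in W1, 2.63 in W3 and 2.2 in W4 (adjusted p = 2.55e-15). Serpina1b reached 2.15 ± 0.13 in W2, and Serpina10, an inhibitor acting on coagulation factors with protein Z, lay on side B with 2.01 ± 0.13 in W2. Serpina1 genes share much sequence, so their probes may bind more than one of them and the values of single members are uncertain. Pttg1, the securin that restrains separase until anaphase, differed most in W1, at 2.43 ± 0.10 on side B against 0.70 to 0.90 in the other mice (adjusted p = 1.22e-10). Ighg2c, an immunoglobulin heavy chain constant region, lay at 2.05 ± 0.16 on side A in W2, while W3 and W4 lay there at 0.62 and 0.25 and W1 on side B at 0.10.

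Cyp4a14, a fatty acid omega-hydroxylase induced through PPARalpha, lay on side B in all mice and at 1.63 ± 0.10 in W2. Aldh1a7, an aldehyde dehydrogenase, lay on side B at 1.25 ± 0.14 in W1 and 1.08 in W2, and on side A at 0.48 in W3 and 0.25 in W4. Hspa1a, the stress-inducible Hsp70, lay on side B in all mice with sizes of 1.08, 0.73, 0.73 and 1.38 ± 0.21 in W1 to W4 (adjusted p = 0.000213). Igfbp3, which carries insulin-like growth factors, lay on side A at 1.07 in W2 and 1.23 ± 0.07 in W4, against 0.47 in W1 and 0.26 in W3. Fbln5, an elastic fibre protein, followed a like order with 1.22 in W2 and 1.21 in W4, against 0.70 in W1 and 0.48 in W3. Rdh16f2, Tmem238 and Gadd45g had ranges of 1.1, 1.08 and 1.07, all on side B. Gclc, the catalytic subunit of glutamate-cysteine ligase, had a range of 1.05 and lay farthest from W5 in W3, but its other probe lay on side B in all 4 mice with sizes of 1.19 to 1.61 and is dim (technical SD 0.711), so the probes disagree. Nup155, Ucma and Mark3 ranged over 1.08, 1.02 and 0.99 with the profile of a probe listed with several beta-globin genes, which Cdca8 and Tap1 also shared, and the other Mark3 probe was not called (range 0.26, adjusted p = 0.388). Actb, the control that was measured, had a range of 0.31 and was not called (adjusted p = 0.661).

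In all, limma called 629 of 15715 probes in the 5-kidney test (4.00%), against 2806 at an unadjusted p under 0.05. The median range of called probes was 0.52, with 232 over 1.5-fold and 36 over 2-fold. They included 336 named genes, 21 probes listed with several genes and 217 unnamed here. By the kidney farthest from the median of the others, W4 had 173 of the called probes, W2 167, W5 135, W3 94 and W1 60. Residual SDs ran from 0.208 to 0.231 over the arrays of W4 and from 0.153 to 0.174 over those of W1. Unequal array noise may thus enter these counts. The 5-kidney count fell to 403 without the dye term. A fit with 1 probe per named gene called 383 of 8005, against 336 of the same genes in the main fit. Without mouse W1 the 5-kidney count was 378, and without mouse W2 335.

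**Figure D1:**
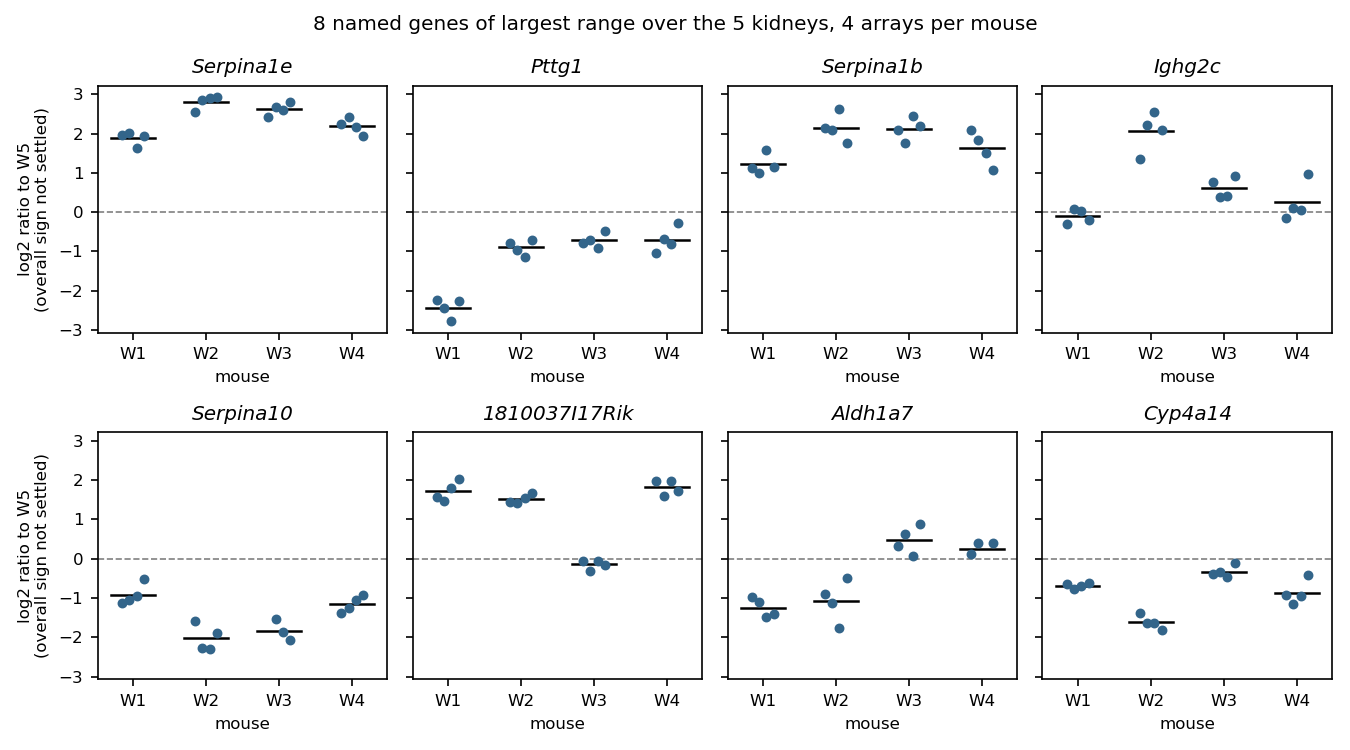
Log2 ratio against W5 of the 8 named genes of largest range, 1 panel per gene; points are the arrays of each mouse with a value, horizontal lines are the mouse means, the dashed line is W5, and the overall sign is not settled. Serpina1e lies on one side of W5 in all 4 mice, and Pttg1 lies farthest from W5 in W1.

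The second comparison took W5 out of the question and asked what differed among W1, W2, W3 and W4. 1810037I17Rik set W3 apart, with a size of 0.14 on side B in W3 and 1.51 to 1.81 on side A in the other mice, so that it ranged over 1.96 among the 4 (adjusted p = 4.11e-07). Ighg2c ranged over 2.15 with W2 apart, and Pttg1 over 1.72 with W1 apart (adjusted p = 0.000208 and 3.47e-06). Azgp1, zinc-alpha-2-glycoprotein, lay on side A at 0.90 ± 0.07 in W2 and on side B at 0.50 in W1, a range of 1.4 (adjusted p = 2.52e-06). Aldh1a7 ranged over 1.72 and Cyp4a14 over 1.3.

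Each mouse had genes that set it apart from the median of the other kidneys. In W1 these were Pttg1 by 1.72, Aldh1a7 by 1.37, the fibrillar collagen gene Col27a1 by 0.71, the stearoyl-CoA desaturase gene Scd1 by 0.69 and S100a11 by 0.60. W2 lay apart in Ighg2c by 1.93, in Cyp4a14 by 1.12, in Alad, an enzyme of haem synthesis, by 0.98, in the aminoacylase gene Acy1 by 0.95 and in Azgp1 by 0.91. W3 lay apart in 1810037I17Rik by 1.76, in Gclc by 0.93, in the nuclear receptor gene Ppard by 0.78, in Odc1, the rate-limiting enzyme of polyamine synthesis, by 0.70 and in the adaptor gene Sh3bp2 by 0.66. W4 lay apart in Igfbp3 by 0.86, in Ucma, Acox2 and Pnmal1 by 0.82 each and in Cdca8, a chromosomal passenger protein, by 0.78. A large distance from this median did not mean that a kidney lay alone. In 1810037I17Rik, W3 lay only 0.14 from W5. Aldh1a7 lay on side B at 1.08 in W2 beside 1.25 in W1, and Scd1 at 0.62 in W3 beside 0.75 in W1. Sh3bp2 lay on side A at 0.63 in W4 beside 0.68 in W3, and Igfbp3 at 1.07 in W2 beside 1.23 in W4. Among W1 to W4 alone Cdca8 was not called (adjusted p = 0.179). Pnmal1 lost its 5-kidney call in 4 of 20 alternative settings, among them without W4.1, without W4.3 and without the 2 dimmest arrays. The limma F test among W1 to W4 called 110 probes (0.700%), with 1751 at an unadjusted p under 0.05. All 110 were also called in the 5-kidney test, and they covered 66 named genes. Their median range was 0.81, and 96 exceeded 1.5-fold. The count was 243 with array weights, 62 without the dye term and 72 without array W3.2. It was 54, 53, 49 and 70 with W1, W2, W3 and W4 left out in turn.

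The third comparison took the kidneys in pairs. The widest pair differences of named genes came from the same transcripts, with Serpina1e 2.81 apart between W2 and W5 and Pttg1 2.43 apart between W1 and W5. Ighg2c was 2.15 apart between W1 and W2, and 1810037I17Rik was 1.96 apart between W3 and W4. Against W5, limma called 125 probes in W1, 368 in W2, 93 in W3 and 316 in W4. The fit gave all arrays the same error variance, while residual SDs were 0.208 to 0.231 in W4 and 0.153 to 0.174 in W1. With a common median absolute deviation, W1 had more calls against W5 than W4. The count of W4 also fell without the 2 dimmest arrays, so this order depends on array noise. Between mice measured on separate arrays it called 29 probes for W1 and W2, 25 for W1 and W3, 37 for W1 and W4, 47 for W2 and W3, 43 for W2 and W4, and 44 for W3 and W4. Differences between mice carry the error of both sets of arrays, so their counts do not compare with those against W5. Leaving out 1 array moved the count of each pair by over 1.5 times at least once, and that of W1 and W3 to as few as 9.

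**Figure D2:**
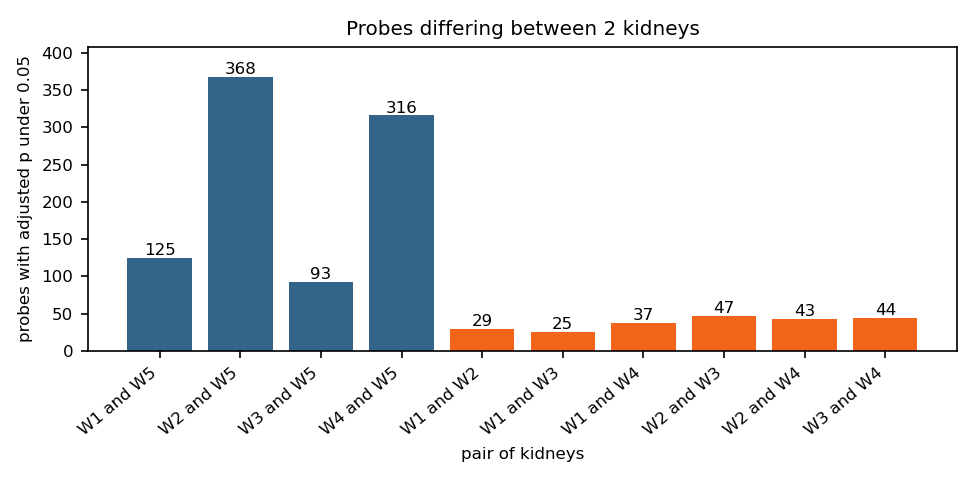
Number of probes with an adjusted p under 0.05 for each of the 10 pairs of kidneys, on an axis starting at 0; blue bars are pairs compared on the same arrays and orange bars are pairs compared through W5. The counts run from 25 to 368, and the pairs of W2 and W4 with W5 have the highest. The order of W1 and W4 against W5 turned with a common median absolute deviation.

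The fourth comparison asked what set W5 apart from its 4 littermates, with the mouse as the replicate. Serpina1e was the named gene of largest mean size, 2.38 ± 0.42 (SD over n = 4 mice), on side A in 4 of 4 mice (limma adjusted p = 2.38e-05). Serpina1b followed with 1.78, Fbln5 with 0.90, the zinc finger gene Plagl2 with 0.78 and Nr1h4, the bile acid receptor FXR, with 0.61. On side B were Serpina10 with 1.48 ± 0.53, Hspa1a with 0.98 ± 0.31, Rdh16f2 with 0.81, Gadd45g with 0.72 and the lipid droplet gene Cidec with 0.56. Both Nr1h4 probes were called, the second at 0.45 (adjusted p = 0.0116), while the second Plagl2 probe was not (0.06, adjusted p = 0.688). Dnajb1, an Hsp40 that works with Hsp70, lay at 0.49 ± 0.12 on side B, and Fabp4, the adipocyte fatty acid binding protein, at 0.52 ± 0.17 on side B. The test called 45 probes, of which 18 exceeded 1.5-fold, with 2111 at an unadjusted p under 0.05. W5 is a single animal whose own spread is left out; with a spread added for it, 3 probes stayed past the threshold (adjusted p = 0.0444), namely Serpina1e, a probe listed with several serpin genes and the other, dim Gclc probe, at a mean of 1.33 on side B. The count was 27 without mouse W1, 16 without mouse W2 and 461 with all 16 arrays and the mouse as a random block. The fitted correlation of the arrays of a mouse was -0.000756, so this block had next to no effect. The 461 thus treats the 16 repeat hybridisations as independent replicates and is not a count over mice.

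The fifth comparison set the lists of related genes against all named genes, of which 4.2% were called. Fisher's exact test treats genes as independent. Its p-values may be too small where list members vary together or cross-hybridise. Genes of glutathione and xenobiotic metabolism had 7 of 21 measured members called and 10 adjusted over the list alone (Fisher's exact test, adjusted p = 0.000402). Besides Aldh1a7 and Gclc they included Gsta2, a glutathione transferase, with a range of 0.79, and the cytochrome P450 gene Cyp2d9 with 0.76. Cyp2d26 was called too, with a profile close to that of Cyp2d9 (cosine 0.980). Heat shock and chaperone genes had 5 of 15 members called, and all 5 lay on side B in the 4 mice. Besides Hspa1a these were Dnajb1, Hspb1 and Bag3, with ranges of 0.66, 0.52 and 0.50, and Cryab. Their count was 6 adjusted over the list alone, with an adjusted p of 0.00115. Adipose markers had 5 of 11 called, 6 adjusted over the list alone (adjusted p = 0.000474). Fabp4, Cidec and Car3 lay on side B in all mice, while Scd1 and Lpl, the lipoprotein lipase, lay on both sides.

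Endothelium and stroma markers had 6 of 20 called, 12 adjusted over the list alone (adjusted p = 0.000616). Esm1, an endothelial proteoglycan, lay on side A at 0.54 ± 0.08 in W2 and 0.74 ± 0.08 in W4, against 0.14 in W1 and 0.04 in W3. Emcn, the endothelial sialomucin endomucin, lay at 0.51 in W2 and 0.59 in W4 against 0.03 and 0.04. Egfl7 and Mgp had ranges of 0.54 and 0.51. Markers of the third segment (S3) of the proximal tubule had 5 of 12 called, 7 adjusted over the list alone (adjusted p = 0.000589). Slc22a7, an organic anion transporter, lay on side B at 0.53 in W2 and 0.50 in W4. It lay at 0.05 on side B in W1 and 0.02 on side A in W3. Slc17a3, Gramd1b and Slc5a1 had ranges of 0.52, 0.46 and 0.43. Slc17a3 lay on side A in all mice, but Gramd1b and Slc5a1 lay on side B. Markers of the earlier proximal segments had 3 of 11 called, also 3 adjusted over the list alone (adjusted p = 0.0217), namely Aqp1, Slc7a7 and Ass1 with ranges of 0.47, 0.39 and 0.33. Ass1 was at the threshold (adjusted p = 0.0492) and lost its call in 15 of 20 alternative settings. Collecting duct and medulla markers had 4 of 17 called, 5 adjusted over the list alone (adjusted p = 0.0127). These were the water channel gene Aqp2, Napsa, the pendrin gene Slc26a4 and Foxi1, a regulator of intercalated cells, with ranges of 0.59, 0.56, 0.38 and 0.29. They did not move together, as Slc26a4 lay on side A in all mice, Foxi1 on side B, and Aqp2 on both sides. Napsa also lay on side B, but its place in this list was not checked against kidney cell types. Glomerulus markers had 3 of 7 called, 5 adjusted over the list alone (adjusted p = 0.00678), with Podxl, a podocyte surface protein, at 0.68, Ehd3 at 0.45 and Npnt at 0.29. Podxl lay on side A in all mice, Npnt on side B and Ehd3 on both sides. The other Ehd3 probe was not called (adjusted p = 0.624), and Ehd3 lost its call in 7 of 20 settings.

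Regulated genes formed further groups that varied. Immediate early genes had 5 of 13 called, 6 adjusted over the list alone (adjusted p = 0.000616), with Gadd45g at a range of 1.07, the matricellular gene Ccn2 at 0.82, Ier3 at 0.51 and Gadd45b at 0.43. The other Gadd45b probe had a range of 0.12 and was not called (adjusted p = 0.366). Ccn2 lay on side A at 0.77 in W2 and 0.68 in W4, against 0.05 on side B in W1 and 0.14 on side A in W3. Glucocorticoid responsive genes had 4 of 13 called and 10 adjusted over the list alone (adjusted p = 0.00538), with Fkbp5, a glucocorticoid receptor co-chaperone, at 0.59, Errfi1 at 0.58, Cdkn1a, a cyclin-dependent kinase inhibitor, at 0.57 and the metallothionein gene Mt2 at 0.44. Androgen responsive kidney genes had 4 of 12 called, 7 adjusted over the list alone (adjusted p = 0.00433), with Odc1 at 0.90, Slc22a7 at 0.54, Hsd11b1, which regenerates active glucocorticoid, at 0.71 and Cndp2 at 0.34. The other Cndp2 probe was not called (range 0.39, adjusted p = 0.0772), and Cndp2 lost its call in 13 of 20 settings. Major histocompatibility (MHC) genes had 3 of 9 called, 5 adjusted over the list alone (adjusted p = 0.0127). The class II genes H2-Eb1 and H2-Aa lay on side A at 0.44 and 0.46 in W4 and at 0.38 and 0.46 in W2, and Tap1, a peptide transporter, had a range of 0.67. Tap1 is counted in the list although its probe shares the beta-globin profile, and it lost its call in 9 of 20 settings. Cholesterol and lipid synthesis genes had 3 of 12 called, and 3 adjusted over the list alone (adjusted p = 0.0260), with Scd1 at 0.87, Cyp51 at 0.49 and the fatty acid synthase gene Fasn at 0.41. Genes known to vary among normal mice from earlier work had 5 of 10 called, 6 adjusted over the list alone (adjusted p = 0.000402), with Cyp4a14, Hspa1a, Igfbp3, Fkbp5 and the cytokine signalling inhibitor Cish at a range of 0.93.

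The remaining 16 lists did not pass. Called members and measured members numbered 2 and 8 for the distal tubule (Sfrp1 and Emx1, ranges 0.40 and 0.28), 2 and 11 for the circadian clock (Bhlhe40 and Usp2, 0.60 and 0.31) and 3 and 25 for the cell cycle (Cdca8, Mcm7 and Ccnd1, 0.88, 0.53 and 0.52). They numbered 2 and 18 for kidney injury and inflammation, where Clu and Lgals3 had ranges of 0.45 and 0.29 and lost their calls in 16 and 18 of 20 settings. A single member was called among 9 loop of Henle markers (Aqp1), 10 interferon response genes (Rsad2, range 0.55), 14 muscle markers (Mylk, 0.32), 15 genes of PPARalpha and fatty acid oxidation (Cyp4a14), 18 strain-polymorphic genes (Cyp2d9) and 19 leukocyte markers (Iglv1, 0.32). Adjusted over the list alone, the counts of these lists were 3 for the distal tubule, 4 each for the clock, cell cycle, injury, loop of Henle and strain-polymorphic lists, 5 for PPARalpha, 2 for interferon and 1 each for muscle and leukocytes. Usp2 and Mylk lost their calls in 16 settings each, Sfrp1 in 14 and Emx1 in 7. The other Iglv1 probe was not called (adjusted p = 0.258). No member was called among 59 oxidative phosphorylation genes, 42 ribosomal protein genes, 14 housekeeping genes, 9 renin-angiotensin and vasoactive genes, 7 adrenal markers and 6 red blood cell markers. Adjusted over the list alone, 1 renin-angiotensin gene passed and 0 of each of the others. Fisher adjusted p-values of these 16 lists started at 0.0832.

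Shifts of whole lists in single pairs were small. Camera with a preset correlation called 58 of 300 list and pair tests, and 0 of 300 held with an estimated correlation. Endothelium and stroma markers differed between W2 and W5 by a mean of 0.23 (adjusted p = 4.88e-06, and adjusted p = 0.0662 with an estimated correlation). They differed between W4 and W5 by 0.20 (adjusted p = 7.64e-05, and adjusted p = 0.0788 with an estimated correlation). Ribosomal protein genes, with no member called singly, differed between W1 and W4 by 0.22 (adjusted p = 3.23e-12, and adjusted p = 0.0866 with an estimated correlation). Oxidative phosphorylation genes differed between W2 and W3 by 0.15 (adjusted p = 7.23e-07, and adjusted p = 0.387 with an estimated correlation). Glucocorticoid responsive genes differed between W1 and W5 by 0.22 (adjusted p = 3.59e-06, and adjusted p = 0.0662 with an estimated correlation). Adipose markers differed between W3 and W5 by 0.28 (adjusted p = 7.64e-05, and adjusted p = 0.0662 with an estimated correlation). The Fisher calls of the cholesterol, MHC, glomerulus, early proximal tubule and collecting duct lists ended under at least 1 alternative, with adjusted p-values of 0.165, 0.107, 0.0713, 0.132 and 0.286 at the highest.

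**Figure D3:**
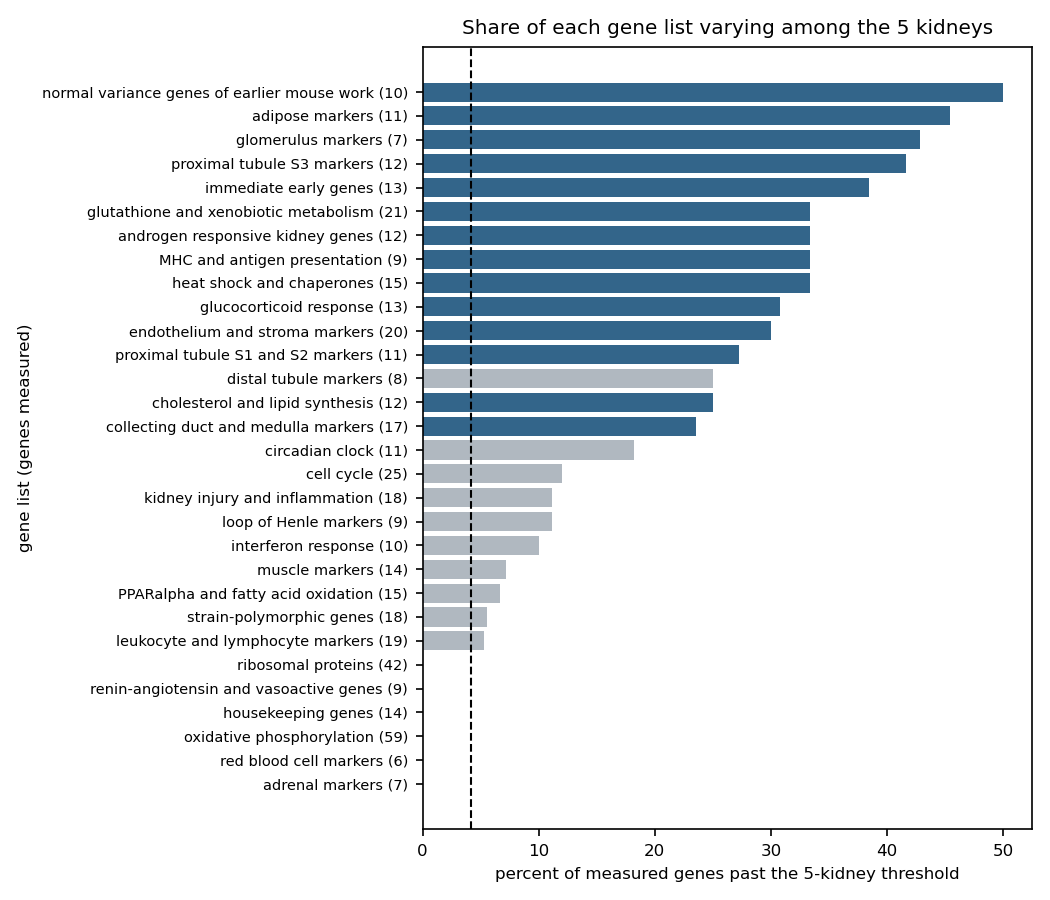
Percent of measured members called in the 5-kidney test for each gene list, on an axis starting at 0; blue bars passed Fisher's exact test at an adjusted p under 0.05 and the dashed line marks the 4.2% of all named genes that were called. The list of genes known to vary among normal mice stands highest with 5 of 10 called, and 6 lists stand at 0.

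The last comparison measured the dye effect and the error of the assay. The dye term was called for 1959 probes (12.5%) with a median size of 0.18 and a largest size of 0.52, so 0 exceeded 1.5-fold. Of the probes called in the 5-kidney test, 112 also had a dye effect, against 78.4 expected for independent calls. The technical SD of 1 array had a median of 0.195 ± 0.0103 (jackknife SE over 16 arrays), and that of a mean over 4 arrays was 0.0973. The between-kidney SD, taken over W1 to W4, was 0.0317 ± 0.0245 from the median variance, less than 2 SE above 0. From the mean variance over probes it was 0.0682, against a technical SD of 0.229. Such variance estimates are skewed over probes, so their median tends to lie low and does not settle the variation of the typical probe. For called probes the between-kidney SD had a median of 0.199 and the technical SD 0.165. Dim probes had a technical SD of 0.267 and other probes 0.185. The count of dye effects was 572 after a running median over probe numbers was taken off.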

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

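The tests of sequence shared with beta-globin, of blood, of the share of tubule cells and of a trend over probe numbers as the whole cause were chosen only after the result was seen, and those of blood and of tubule cells were reworded after a first result; the running median and the fit without the dimmest arrays were also chosen after the data were seen.

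Other groupings of the arrays were fitted to ask whether chance can be excluded. For the 5-kidney test, only the real grouping, 1 of 81 ways to pair the 4 arrays of each mouse into orientations, gave as many as 629 probes, and the highest of the others gave 281. For W1 to W4, 1 of 100 groupings gave as many as 110 probes, the highest of the others 13. For each of the 6 pairs among W1 to W4, 1 of 35 splits of the 8 arrays gave as many as the real one. The highest of the other splits gave 0 for W1 and W2, 1 for W1 and W3, 2 for W1 and W4, 0 for W2 and W3, 3 for W2 and W4, and 2 for W3 and W4, against real counts of 29, 25, 37, 47, 43 and 44. Of the 81 pairings, 1 gave as many as 14 lists past Fisher's test, the highest of the others 6. A random arrangement of the arrays is thereby excluded as the source of these counts, at a share under 0.05. The regrouping cannot tell the RNA extract from anything else that the 4 arrays of a mouse share. The count of lists rests on the called probes and is not separate support, and false calls among the 629 are not addressed. The 58 camera tests are less distinct, since 3 of 81 pairings gave as many and 1 of them gave 63.

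Of the genes picked by the naming rule, 37 differed among the 4 mice by the F test of W1 to W4, which called 66 named genes in all, and the ranges of these 37 were as follows. Ighg2c ranged over 2.15, 1810037I17Rik over 1.96, Pttg1 and Aldh1a7 over 1.72 each, Azgp1 over 1.4, Cyp4a14 over 1.3 and Serpina10 over 1.09. Ranges were 1.08 for Nup155, 1.05 for Tmem238 and Gclc, 1.03 for Alad, 1.02 for Ucma, 0.99 for Mark3 and Acy1, and 0.97 for Igfbp3. Serpina1b, Cish and Serpina1e had 0.94, 0.93 and 0.92. Odc1 had 0.90, Pnmal1 0.89, Ppard 0.88, Scd1 0.87, Col27a1 0.85, Acox2 0.84 and Ccn2 0.82. Gsta2 had 0.79, Gadd45g 0.76, Cyp2d9 0.75, Fbln5 0.74, Sh3bp2 0.72, and Esm1 and S100a11 0.70 each. Fkbp5 had 0.59, Emcn 0.56, Rsad2 0.55, Slc22a7 0.54 and Egfl7 0.54.

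A single array lay far from the other 3 of its mouse in 10 of 335 groups, where chance gives about 1 in 20, or 16.75. The gap to the nearest array, as a share of the group's range, was 0.858 for Hspa1a in W1, 0.895 for Fabp4 and 0.957 for Lgals3 in W2. In W4 it was 0.860 for Tmem238, 0.838 for Gadd45g, 0.900 for Dnajb1, 0.848 for Aqp1, 0.848 for Foxi1 and 0.890 for Egfl7. For the residual SD of the arrays of W1 it was 0.935, with 0.174 for array W1.2 and 0.153 to 0.154 for the others.

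A first pattern is that 25 called probes share the profile of a probe listed with several beta-globin genes (cosine of at least 0.95 and at least 0.5 of its size), which had sizes of 0.93, 0.78 and 0.51 on side A in W1, W2 and W3 and 0.15 on side B in W4; 11 have 1 named gene, among them Nup155, Ucma, Mark3, Cdca8 and Tap1. Of 3 other probes of these genes, for Rlf and Mark3, 0 was called with a cosine of at least 0.95 (the nearest, for Rlf, had 0.835 at 0.225 of the size, adjusted p = 0.449), so globin sequence or a wrong clone at these spots may account for their sharing it. More blood in some kidneys stays open as a source of the profile itself: a probe listed with several alpha-globin genes and another gene also followed it, at 0.61 of the beta-globin size (adjusted p = 0.00589), while the 6 red cell genes moved by -0.0132 ± 0.0398 but include only 1, Alas2, that kidney cells do not also express, and it did not follow (cosine 0.0485, adjusted p = 0.647). After a running median over probe numbers was taken off, the mean size of the 25 was 0.706 ± 0.0281 of the beta-globin size. Before, it was 0.743, and 88% of the 25 were still called. These values argue against a trend over probe numbers as the whole cause. Here and for the red cell genes, ± is an SE over probes or genes. Those are not independent replicates, so it may be too small. Local bias of another shape stays open, since 13 of the 25 and the alpha-globin probe have numbers between 15318 and 15614, though Alas2 at 15517 lies there too and does not follow, and a biological explanation other than blood was not tested.

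A second pattern is that endothelium and stroma markers lay toward side A in W2 and W4 relative to W1 and W3. Their mean was 0.18 ± 0.05, with 17 of 20 genes on that side. Values after ± in this paragraph are SE over genes, which are not independent replicates, so they may be too small. A different share of tubule cells in W2 and W4 would move markers of all other cell types alike, whichever side is the higher. Leukocyte and muscle markers stayed behind by 0.155 ± 0.0491. This cannot decide, since probes of genes hardly expressed in kidney would stay near 0 in either case, and no intensities were used here. The between-kidney variance of leukocyte markers stood at the percentile 0.15 of random lists. MHC genes (0.17 ± 0.07), ribosomal proteins (0.11 ± 0.01) and glomerulus markers (0.08 ± 0.07) had means toward side A as well. Of the tubule lists, S3 (-0.10 ± 0.04), distal tubule (-0.05 ± 0.03), collecting duct (-0.02 ± 0.02) and loop of Henle (-0.01 ± 0.05) had means toward side B. That is opposite to endothelium and stroma, as a different share of tubule cells would give. The earlier proximal segments (0.07 ± 0.05) lay toward side A, so such a share stays open. The mean of the endothelium and stroma list was 0.163 ± 0.0423 after the running median, 89.4% of its size, and 116% was kept without the 2 dimmest arrays, which argues against a trend over probe numbers and against these arrays as the whole cause. Local bias that does not follow probe numbers, or a difference between the animals in their vessels and stroma or in the piece of kidney taken, could remain and was not tested.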

How the results depend on the processing

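The alternatives that leave out dim probes or the 2 dimmest arrays, or take off a running median, were chosen after seeing the data. For the 85 named genes, signs were compared only where a gene was called in both fits, and only in the mouse farthest from W5. None of these signs turned. Of the 84 called, 60 stayed called in each setting and 66 over all 16 fits with 1 array left out. Those lost in most of the 20 settings were Lgals3 (18), Clu, Mylk and Usp2 (16 each), Ass1 (15), Sfrp1 (14) and Cndp2 (13). The range of 4 genes moved by over 1.5 times: with the running median Mcm7 had 0.31 and Fasn 0.27, both uncalled (adjusted p = 0.254 and 0.267), and without the 2 dimmest arrays Cidec had 1.3 and Clu 0.29 (also without W4.4). Mcm7 also lost its call without W2.1, W2.2 or W2.4, and Fasn without W2.1 or W2.2 or with a common median absolute deviation. Of the alternatives counted over whole comparisons, 282 values kept within 1.5 times or 1 SD and 75 did not; the cause was not tested except where fewer probes, arrays or mice entered. For the 5-kidney test the count was 403 without the dye term, 383 with 1 probe per named gene and 275 at an adjusted p under 0.01. For W1 to W4 it was 62 without the dye term, 243 with array weights and 60 at an adjusted p under 0.01. On probes with values on all arrays, W1 and W4 differed at 56 probes and W2 and W4 at 68. With a common median absolute deviation, the counts were 237 for W1 and W5, 176 for W4 and W5, 42 for W1 and W3, and 22 for W2 and W4. Without the 2 dimmest arrays they were 118 for W4 and W5, 21 for W2 and W4, and 18 for W3 and W4. The running median left 572 dye effects. For W5 against its littermates the count was 461 with a random block for the mouse, 3 with a spread added for W5 and 74 with a common median absolute deviation. It was 126 on complete probes, 71 with robust moderation and 113 without dim probes. The random block had next to no effect, so the 461 treats repeat hybridisations as independent replicates. With the spread added, 113 probes had an unadjusted p under 0.05. The technical SD was 0.183 on complete probes and 0.218 without the dye term, where the between-kidney SD was 0. With an estimated correlation 0 list and pair tests passed.

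With the array number as a block in place of the dye term, 591 probes were called in the 5-kidney test, of which 551 were shared with the 629. The numbers do not pair the arrays, since arrays of the same number in different mice correlated at a median of -0.0662 and 0 arrays correlated best with their own number. The block moved no other count by over 1.5 times, but 5 named genes and the glomerulus list (adjusted p = 0.0631) lost their calls.

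Leaving out arrays or mice in turn, the 5-kidney count lay between 335 and 671, with 378 without mouse W1 and 335 without mouse W2. That for W1 to W4 lay between 49 and 125, with 72 without array W3.2, and 54, 53, 49 and 70 without mice W1 to W4. Counts against W5 ran from 54 to 139 for W1 (54, 62 and 57 without W1.1, W1.3 and W1.4), from 183 to 428 for W2 (183, 237 and 206 without W2.1, W2.2 and W2.4), from 46 to 121 for W3 (47 and 46 without W3.2 and W3.4) and from 155 to 395 for W4 (155 and 200 without W4.1 and W4.3). For W1 and W2 they ran from 13 to 34, with 18, 18, 13 and 13 without W1.1 to W1.4 and 18 without either W2.2 or W2.4. For W1 and W3 they ran from 9 to 28, with 11, 9 and 9 without W1.1, W1.3 and W1.4 and 15, 13, 11 and 12 without W3.1 to W3.4. For W1 and W4 they ran from 23, without W1.3, to 51. For W2 and W3 they ran from 30 to 59, with 31 without W2.3 and 30 without W3.3. For W2 and W4 they ran from 25 to 70, with 26, 27 and 25 without W2.1, W2.2 and W2.4, 67 without W3.4, and 26, 70 and 27 without W4.1, W4.2 and W4.3. For W3 and W4 they ran from 22 to 67, with 26, 22 and 23 without W3.1, W3.2 and W3.4 and 67 without W4.2. Dye effects ran from 1267 to 1915, with 1302, 1267 and 1268 without W2.3, W2.4 and W4.1. The count for W5 against its littermates ran from 16 to 61, with 27 without mouse W1 and 16 without mouse W2. The technical SD ran from 0.188 to 0.197 and the between-kidney SD from 0.0229 to 0.0466.

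Among lists, the cholesterol call ended with a common median absolute deviation (adjusted p = 0.165) and the running median (0.144), the glomerulus call with the running median (0.0649) and without the dimmest arrays (0.0713), and the early proximal tubule call with the running median (0.132). The MHC and collecting duct calls ended without the dimmest arrays (0.107 and 0.286). Brightness limits the precision, as dim probes had a technical SD of 0.267.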

Other observations

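The 2 tests of neighbouring genes were chosen before their results were seen, while the contrast of W2 and W4 with W1 and W3 was chosen only after the result was seen.

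No ribosomal protein or oxidative phosphorylation gene was called. Relative to W1 and W3, W2 and W4 lay toward side A for 41 of 42 ribosomal protein genes, with a mean of 0.11 ± 0.01 (SE over genes, which are not independent replicates). They lay toward side B for 43 of 59 oxidative phosphorylation genes and toward side A for the other 16, with a mean of -0.05 ± 0.01. No camera call of either list held with an estimated correlation, where the lowest adjusted p was 0.0866 for ribosomal proteins and 0.387 for oxidative phosphorylation. MHC genes lay toward side A with a mean of 0.17 ± 0.07 in 8 of 9 genes, and heat shock genes toward side B with 0.05 ± 0.02 in 12 of 15. These values were not tested against chance, and the mean of all named genes was 0.01. Among random lists of the same size, the median between-kidney variance of the genes known to vary in normal mice stood at the percentile 100, that of glucocorticoid responsive genes at 99.98, of endothelium and stroma markers at 99.89, of circadian clock genes at 99.87, of ribosomal proteins at 99.45, of heat shock genes at 52.27 and of leukocyte markers at 0.15.

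On a mixed background, chromosome segments of C57BL/6 and 129Sv can differ between littermates, and neighbouring genes could then vary together. Over 69 pairs of called genes within 10 places of each other on assembly GRCm38.p6, the mean cosine of profiles over the kidneys was 0.162 (one-sided permutation p = 0.0307). With pairs of the same gene family left out, 59 pairs remained, with a mean of 0.10 and a one-sided permutation p of 0.150. Family members that cross-hybridise may account for part of the excess, as with Cyp2d9 and Cyp2d26 (cosine 0.980) or Serpina1b and Serpina1e (0.997). Other family pairs went against this, with -0.995 for Serpina10 and Serpina1b, -0.989 for Serpina10 and Serpina1e, and 0.417 for Rdh16 and Rdh16f2. Without families the mean still lay above the median of 0.00730 of shuffled genes. Segregating segments stay open, since pairs of the same segment that differ in opposite directions cancel in this mean. The mean cosine therefore cannot decide for or against them, and no genotypes were used here.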
